A study of Homo sapiens with 2 samples.

How the data were processed

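RNA fragments that end in a cyclic phosphate were measured in 2 libraries from A549 cells, an established human lung carcinoma epithelial line. One library came from cells that received the transfection reagent Lipofectamine alone (mock) and one from cells transfected for 1 h with poly I:C, a synthetic double-stranded RNA, at 1 µg/mL. Per the labels' protocols, total RNA was ligated to an adapter with RtcB, an RNA ligase that joins a cyclic phosphate end to a 5′-hydroxyl end. The ligated RNA was then reverse transcribed from the adapter, circularised, amplified by PCR and sequenced, without a selection of short RNAs. Amplified reads without molecular identifiers are not independent molecules, and no identifier is described. Every interval given here therefore covers only the counting error of reads taken as independent, and can be too narrow for molecules.

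The deposited values are counts, per the file headers: reads per position of 18S rRNA and of 28S rRNA for each library, neither normalised nor pooled. The submitters' processing notes name the build hg19. The aligner, the counting step and the rRNA sequences used as targets are not given in the sources used here. The file headers do not say whether a position is the last nucleotide of a fragment or whether numbering starts at 0 or 1, so positions are printed as deposited and no genome coordinates are attached to them. Each rRNA is encoded by many near-identical repeats, so a position stands for all copies together. The table lists 1690 positions of 18S rRNA and 3357 of 28S rRNA, and each has at least 5 reads in at least 1 library. Another 230163 rows of the table hold no position. The authors' deposited fold is a ratio of the poly I:C reads plus 0.5 over the mock reads plus 0.5, which equalled the value recomputed from the counts in every row, with a largest relative deviation of 0. It is not scaled for library size. The authors' score, by which the table is sorted, is that fold multiplied by the poly I:C reads per the file headers, and was not used.

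The listed reads summed to 3079346 in the mock library and 3764202 in the poly I:C library. These sums cover listed rRNA positions, not the whole libraries, whose depth is unknown. Counts were divided by the library's sum of listed reads and multiplied by 1000000, and the ratio of poly I:C over mock was taken at each position. Its 95% interval is the exact conditional binomial (Clopper-Pearson) interval for a pair of Poisson counts, and shares carry exact Clopper-Pearson intervals. Where a library had 0 reads, the ratio was computed against a floor of 3 reads in that library and is given as a bound. Ranks use the same floor. Counts of 1 or 2 reads were kept as they are, so a position with 1 mock read can rank above one with 0. Positions with at least 100 reads over both libraries, 2750 in all, were compared. They hold 98.9% of the mock reads and 98.8% of the poly I:C reads. With 1 library per group there is no replicate spread and no test between conditions, so no p-value is given. "Higher" and "lower" counts follow a rule of size, a ratio of at least 2 or at most 0.5. They describe these libraries only.

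Lists of positions were set against 10000 random lists of the same size, matched on mean reads in 10 bins. Consecutive windows of 100 nt were summed. The rule for the named sites, the main comparisons of the report and most alternatives were fixed before the data were examined. Among what was added afterwards are the check of other 28S lengths, 18S shares without frequent sites, and the tests of observations outside the report except that of random placement. In each rRNA the named sites are the 8 positions with the highest ratio and the 4 with the lowest ratio among those compared, the 5 with the most reads in each library, and the annotated 3′ end. Other positions were chosen after their values were seen and are named as such. The annotated lengths of the mature rRNAs, 1869 nt for RNA18SN5 and 5070 nt for RNA28SN5, came from the RefSeq gene table of GRCh38.p14. They were used to locate the 3′ ends and to tell which positions and windows lie inside the annotated rRNA. No coordinate of that build was used.

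The ratio and its interval were tested on simulated data with 5047 positions drawn from the mock counts, of which 200 were changed by known ratios. Of the changed positions compared, 100% at a true ratio of 3, 10, 100 or 0.333 passed the 2-fold rule. Of 2523 unchanged positions, 0% passed, and the interval held the true ratio of 1 in 96.0%. Both libraries were simulated as Poisson counts, the spread that the interval assumes, without amplification or differences between libraries. These rates therefore check the calculation and do not give the rate of false calls in the real data. Alternatives were 3 other scalings, other read minimums, a higher threshold, counting intervals, summing of neighbouring positions, other window sizes and another pseudocount. The planned comparison of nucleotides and dinucleotides around the cuts was not made, because no rRNA sequence was used here. The calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.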

Results

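Cyclic phosphate-bearing fragments of 18S rRNA, the RNA of the small ribosomal subunit, and of 28S rRNA, the main RNA of the large subunit, were mapped in A549 cells with and without poly I:C. Poly I:C mimics viral double-stranded RNA, and the study asked where such fragments arise during this treatment. RNase L, the endoribonuclease of the double-stranded RNA response, leaves cyclic phosphate ends, as do other RNases and chemical hydrolysis. No nuclease was assigned to a site here, because the labels describe no sample that lacks one. The mock library held 722212 reads on 18S rRNA and 2357134 on 28S rRNA. The poly I:C library held 1292952 reads on 18S rRNA and 2471250 on 28S rRNA. Each condition was represented by 1 library, so no difference reported here has a replicate check.

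The 18S rRNA share of the listed reads was higher in the poly I:C library. It was 23.5% (95% exact binomial interval 23.4 to 23.5) in the mock library and 34.3% (34.3 to 34.4) in the poly I:C library. The unscaled 18S rRNA reads differed 1.79-fold between the libraries and the 28S rRNA reads 1.05-fold. The single window from 18S position 701 to 800 held 4829 mock reads and 338356 poly I:C reads. Without that window the 18S rRNA share was 23.3% in the mock library and 27.9% in the poly I:C library. Without the 14 positions that were among the 10 most frequent of either library, it was 42.2% and 42.6%.

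In 18S rRNA, position 771 showed the highest ratio of the 1090 positions compared. It had 63 reads in the mock library and 224713 in the poly I:C library, a ratio of 2918 (95% counting interval 2281 to 3797) after scaling to the library totals. It alone held 5.97% of all listed poly I:C reads, against 0.00205% of the mock reads. The authors' deposited table gives an unscaled fold of 3539 for this position. Position 770, directly beside it, had 575 mock reads and 91335 poly I:C reads, a ratio of 130 (120 to 141). Of the 8 positions with the highest ratios, 7 lay between positions 767 and 776. Besides 770 and 771 these were position 767 at a ratio of 159 (61.8 to 585), position 768 at 126 (80.3 to 209) and position 772 at 120 (69.9 to 225). Position 775 had 1 mock read and 452 poly I:C reads, a ratio of 370 (66.0 to 14637). Position 776 had 0 mock reads and 1272 poly I:C reads, so it was at least 347-fold higher against the floor of 3 mock reads, with a lower 95% counting limit of 282. The 13 positions from 761 to 776 with ratios of at least 10, a set chosen after its values were seen, together had 862 mock reads and 330855 poly I:C reads, a ratio of 314 (294 to 336).

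Outside this segment, position 541 was the remaining member of the 8 highest in 18S rRNA. It had 121 mock reads and 29288 poly I:C reads, a ratio of 198 (166 to 239). Position 136 was the second most frequent 18S site of the poly I:C library, with 118398 reads against 859 in the mock library, a ratio of 113 (105 to 121). Position 130, which lies 6 nt away, had 29916 mock reads and 46284 poly I:C reads, a ratio of 1.27 (1.25 to 1.28) that turned to 0.864 when 18S rRNA was scaled to its own total.

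**Figure D1:**
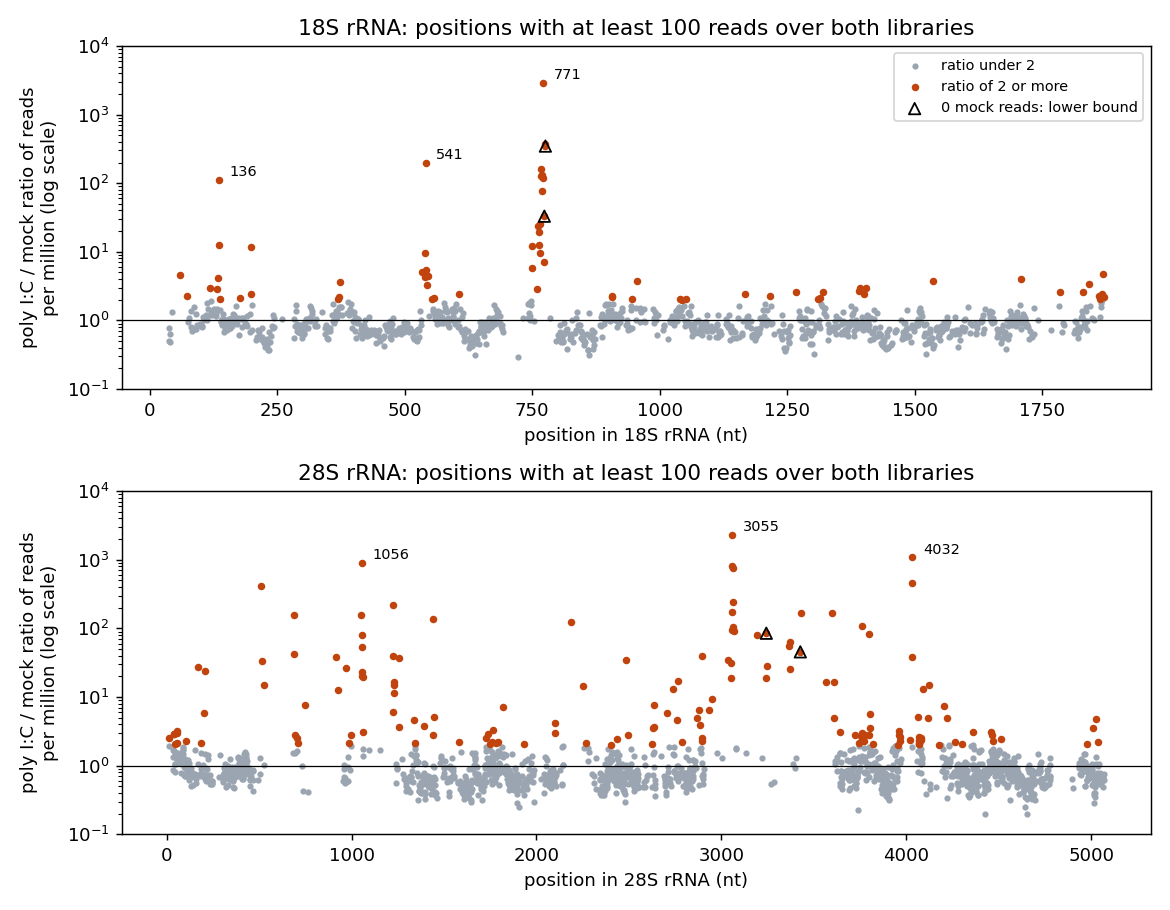
Ratio of poly I:C over mock reads after scaling to the library totals (log axis) against position in 18S rRNA (top) and 28S rRNA (bottom), 1 point per position with at least 100 reads over both libraries. Orange points have a ratio of 2 or more, triangles mark lower bounds where the mock library had 0 reads, and the highest points are 771 in 18S rRNA at 2918 and 3055 in 28S rRNA at 2303.

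In 28S rRNA the highest ratios lay at 4 places along the molecule. Position 3055 had 3 mock reads and 8446 poly I:C reads, a ratio of 2303 (788 to 11170). Another 3 members of the 8 highest lay within 10 nt of it, namely position 3057 at 812 (348 to 2501), position 3063 at 243 (153 to 410) and position 3065 at 764 (402 to 1672). Positions 4031 and 4032 formed an adjacent pair, with 45 and 17 mock reads and 24974 and 22631 poly I:C reads. Their ratios were 454 (339 to 623) and 1089 (680 to 1870). Position 1056 had 66 mock reads and 73429 poly I:C reads, a ratio of 910 (715 to 1177), and was the fifth most frequent 28S site of the poly I:C library. Position 511 had 1 mock read and 499 poly I:C reads, a ratio of 408 (72.9 to 16155). Its place among the 8 highest rests on that 1 mock read.

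**Figure D2:**
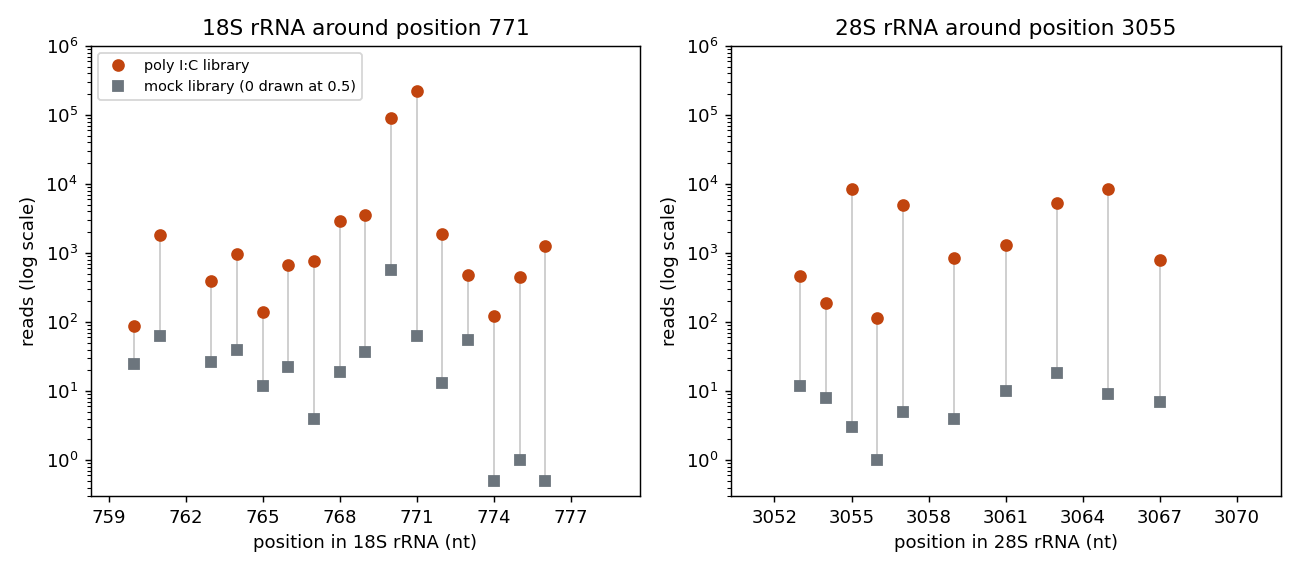
Reads (log axis) at single positions around 18S position 771 (left) and 28S position 3055 (right) in the poly I:C library (circles) and the mock library (squares, with 0 drawn at 0.5), for positions with at least 100 reads over both libraries. Position 771 holds 224713 poly I:C reads against 63 mock reads, and the 28S sites recur every 2 nt.

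By the rule of size, 69 of 1090 compared 18S positions were at least 2-fold higher in the poly I:C library and 68 were at least 2-fold lower. Of 1660 compared 28S positions, 156 were at least 2-fold higher and 209 at least 2-fold lower. Large ratios ran in one direction: 18 positions of 18S rRNA and 60 of 28S rRNA were at least 10-fold higher, and 0 of either rRNA were at least 10-fold lower. The 78 positions at or over 10-fold held 21.2% of the poly I:C reads and 0.194% of the mock reads. The typical position was lower after scaling to the totals, with a median ratio of 0.858 in 18S rRNA and 0.768 in 28S rRNA, a shift of -0.31 on the log2 scale over both. Before scaling, the median ratio of compared positions with reads in both libraries was 0.986, while the listed totals differed 1.22-fold. The shift therefore arose from division by the totals, which include the 78 positions. A lower call need not be a loss of reads. Scaling by the median ratio removed that shift and gave 100 higher and 19 lower positions in 18S rRNA and 218 higher and 71 lower in 28S rRNA. The higher positions made up 50.4% of the 18S calls and 42.7% of the 28S calls under the main scaling, against 84.0% and 75.4% under the median scaling and 9.16% and 64.1% when each rRNA was scaled to its own total.

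**Figure D3:**
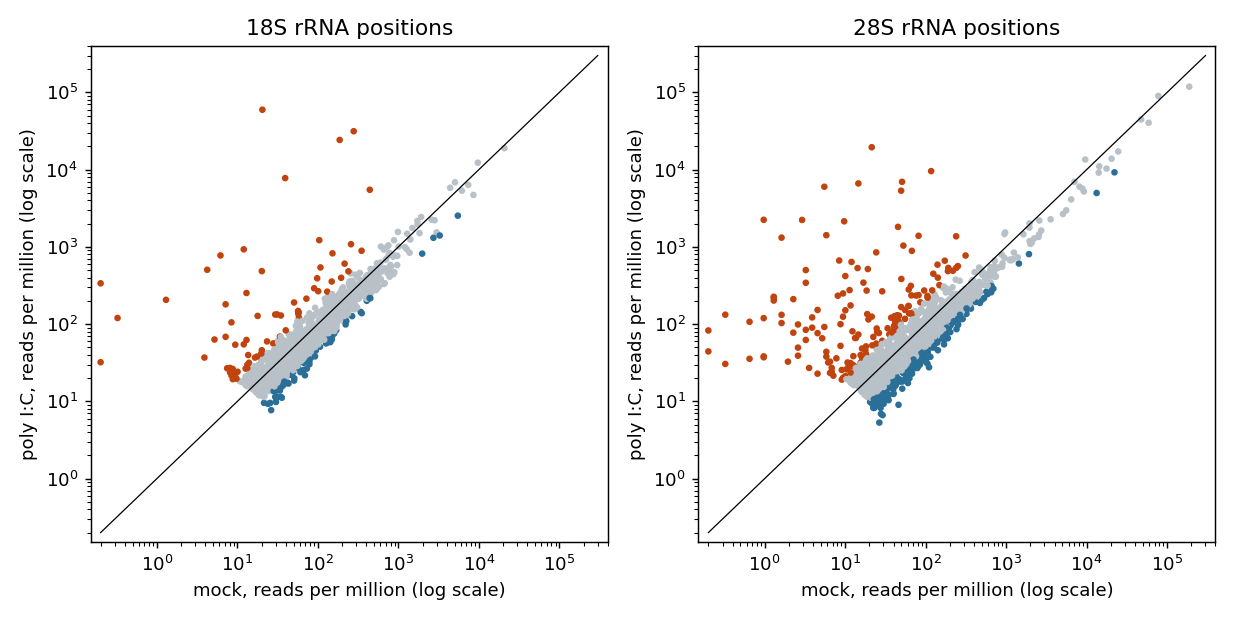
Reads per 1000000 listed reads (log axes) in the mock library (x) and the poly I:C library (y) for each 18S (left) and 28S (right) position with at least 100 reads over both libraries, with 0 drawn at 0.2 and the line of equality. Orange points are at least 2-fold higher (69 and 156), blue points at least 2-fold lower (68 and 209), and grey points lie between.

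The 5 most frequent mock sites of each rRNA had ratios from 0.549 to 1.27 in 18S rRNA and from 0.628 to 1.15 in 28S rRNA, and none of the 10 reached the 2-fold rule, although 18S position 1285 stood at 0.375 when 18S rRNA was scaled to its own total. In 28S rRNA, position 2901 held 18.9% of all mock reads (581421) and 11.9% of all poly I:C reads (446484), a ratio of 0.628 (0.626 to 0.631). Position 4060 had 239988 mock reads and 338799 poly I:C reads, a ratio of 1.15 (1.15 to 1.16). Position 2055 had a ratio of 0.685 (0.680 to 0.690), position 2847 of 0.695 (0.687 to 0.702) and position 4447 of 0.936 (0.929 to 0.942), and that of 4447 turned to 1.16 under the median scaling. In 18S rRNA, position 1374 had 64107 mock reads and 71447 poly I:C reads, a ratio of 0.912 (0.902 to 0.922). Position 1285 stood at 0.549 (0.539 to 0.560), position 1506 at 0.867 (0.850 to 0.884) and position 1721 at 0.860 (0.845 to 0.876). The ratios at 1374, 1506 and 1721 turned to 1.13, 1.08 and 1.07 under the median scaling. The lowest ratios belonged to sites with few reads. In 28S rRNA they were position 4428 at 0.196 (0.131 to 0.286, 142 mock reads), position 4655 at 0.200 (0.116 to 0.328), position 3738 at 0.227 (0.140 to 0.357) and position 4640 at 0.247 (0.153 to 0.387). In 18S rRNA they were position 722 at 0.293 (0.185 to 0.453), position 861 at 0.312 (0.213 to 0.449), position 638 at 0.315 (0.241 to 0.408) and position 1303 at 0.325 (0.216 to 0.481).

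In windows of 100 nt, 15 of 71 were at least 2-fold higher in the poly I:C library and 1 was at least 2-fold lower. No read minimum was applied. Among the 15 is 18S positions 1901 to 2000, past the annotated end, with 8 mock reads and 27 poly I:C reads. Its ratio was 2.76 (1.22 to 7.03). The highest were 28S positions 3001 to 3100 at a ratio of 88.7 (79.1 to 99.8), 28S positions 1001 to 1100 at 86.0 (80.3 to 92.3) and 18S positions 701 to 800 at 57.3 (55.7 to 59.0). 28S positions 3501 to 3600 followed at 23.1 (17.3 to 31.6), on 47 mock reads and 1327 poly I:C reads. The lower window was 28S positions 1601 to 1700 at 0.473 (0.468 to 0.477). The median ratio was 0.955 over the 20 windows of 18S rRNA and 0.931 over the 51 windows of 28S rRNA.

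**Figure D4:**
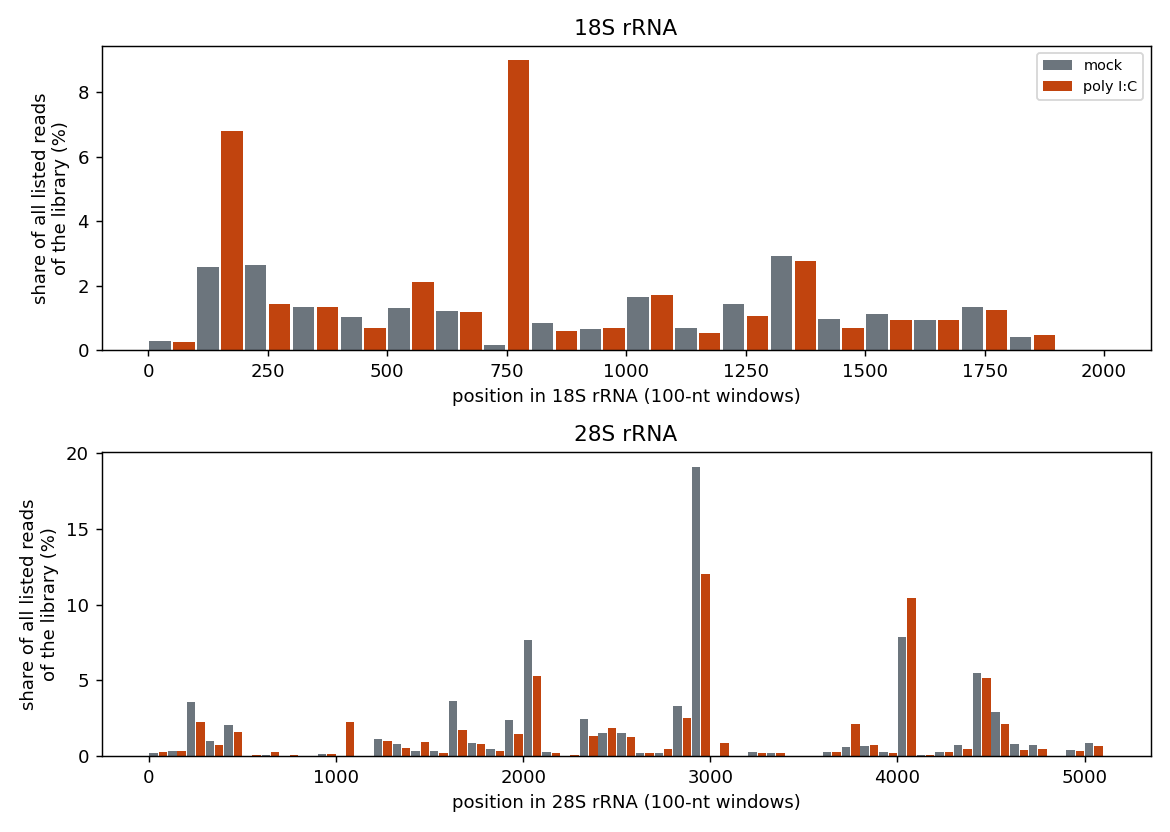
Share of all listed reads of a library (%) in consecutive 100-nt windows of 18S rRNA (top) and 28S rRNA (bottom), mock in grey and poly I:C in orange. The 18S window from 701 to 800 holds 0.157% of the mock reads and 8.99% of the poly I:C reads.

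Positions near the natural 3′ end had higher ratios in 18S rRNA than in 28S rRNA. All 9 compared positions within 10 nt of the annotated 18S end had ratios from 1.14 to 4.81, and all 8 near the 28S end had ratios from 0.485 to 0.744. When each rRNA was scaled to its own total, the 18S values ran from 0.777 to 3.28, and 8 of the 9 stayed above 1, while the 28S values stayed below 1 under all 4 scalings. Position 1869, the last nucleotide of 18S rRNA by its annotated length, had 40 mock reads and 235 poly I:C reads, a ratio of 4.81 (3.43 to 6.90). Position 5070, the last of 28S rRNA by its annotated length, was not listed. Numbering and reference are not given, so position 1869 may not be the true 18S end. Position 1871, among the 9 near it, lies past the annotated end. Of the 17 positions near either end, 5 were at least 2-fold higher and 1 at least 2-fold lower, and their pooled median log2 ratio of 0.19 only reflects 9 positions above 1 mixed with 8 below. The annotated 28S copies are from 5054 to 5077 nt long and the reference behind the positions is not given, so the place of the 28S end is uncertain. With any of these lengths the compared positions within 10 nt, from 2 to 16 of them, had ratios between 0.485 and 0.786, a check added after seeing the data. Over whole molecules, the median log2 ratio was -0.22 in 18S rRNA and -0.38 in 28S rRNA under the main scaling. These became -0.77 and -0.16 when each rRNA was scaled to its own total, so the order of the rRNAs depends on the scaling. Under the main scaling the 18S median lay above all 10000 random lists (percentile 100), and since the 28S list holds all other compared positions, its percentile of 0 is the same contrast. Neighbouring positions are not independent, so these percentiles only describe the libraries. The mean log2 ratio was -0.06 in both.

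The reads were concentrated on few positions in both libraries. The 10 most frequent positions held 49.4% (49.3 to 49.5) of the mock reads and 46.5% (46.4 to 46.5) of the poly I:C reads, and 6 positions were among the 10 in both. The first 11 positions held 50% of the mock reads and the first 13 held 50% of the poly I:C reads. Across the 5047 listed positions, log2 of the reads per 1000000 listed reads plus 1 correlated between the libraries with Pearson's r = 0.885 and Spearman's rho = 0.904. These are correlations across positions, which are not independent replicates.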

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

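The ratios at the 36 named sites were recomputed under 3 other scalings, which gave 108 values. Of these, 67 stayed inside the counting interval and 41 left it. Staying inside depended on the width of the interval, and so on the reads, and is no sign of a more certain ratio. 18S position 775, with its wide interval, stayed under all 3 scalings, and 28S position 2901, with its narrow interval, left under all 3. Each scaling multiplies all ratios of an rRNA by 1 factor, and no factor was large enough to turn a ratio of at least 2 or at most 0.5. Among the ratios between these, the direction turned at 5 of the 36 sites, namely 18S positions 130, 1374, 1506 and 1721 and 28S position 4447. Counts of positions at least 2-fold higher or lower moved more. Scaling by the median ratio gave 19 lower positions in 18S rRNA and 71 in 28S rRNA, and scaling within each rRNA gave 37 higher and 367 lower in 18S rRNA and 111 lower in 28S rRNA. A minimum of 20 reads gave 145 higher and 127 lower in 18S rRNA and 361 and 397 in 28S rRNA, a minimum of 1000 reads gave 24 and 12, and 49 and 34, and no minimum gave 169 and 147, and 456 and 491. A 4-fold threshold gave 30 higher and 0 lower in 18S rRNA and 81 and 4 in 28S rRNA, and a counting interval wholly beyond 2-fold gave 44 and 17 in 18S rRNA and 116 and 73 in 28S rRNA. Summing each position with its neighbours gave 78 higher and 54 lower positions in 18S rRNA and 265 and 254 in 28S rRNA. The median log2 ratio became -0.17 in 18S rRNA and -0.29 in 28S rRNA at 20 reads, -0.17 and -0.42 at 1000 reads, and 0.090 and -0.071 under the median scaling. With each rRNA scaled to its own total it was -0.77 and -0.16, which turned the order of the rRNAs. Of the alternatives chosen after seeing the data, leaving out the 10 most frequent positions of either library gave an 18S share of 42.2% in the mock library and 42.6% in the poly I:C library, and leaving out the window of position 771 gave 23.3% and 27.9%. With 200-nt windows 0% were at least 2-fold lower, and with a pseudocount of 10 Pearson's r was 0.898. Where the cause of a shift is not stated, the cause was not tested. No paired analysis was possible because each group holds 1 library, and for the same reason no replicate could be left out. The planned nucleotide and dinucleotide shares, the fragment length filter and the count of distinct fragments were not run, since the table holds reads per position and no sequence was used. Depth limits the sites with few mock reads: at 18S position 775 the interval of the ratio runs from 66.0 to 14637.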

Other observations

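Strongly higher sites were also found outside the named ones. These were chosen after their values were seen. The 78 positions at or over 10-fold fell into 37 clusters of positions at most 10 nt apart, 5 in 18S rRNA and 32 in 28S rRNA, and 26 clusters were a single position. In 28S rRNA, position 3799 had 361 mock reads and 36053 poly I:C reads, a ratio of 81.7 (95% counting interval 73.7 to 90.9). Position 1443 stood at 137 (117 to 161), position 3763 at 108 (91.7 to 127) and the 5 positions between 1223 and 1231 together at 78.3 (64.1 to 96.7). Position 2894 had 140 mock reads and 6842 poly I:C reads, a ratio of 40.0 (33.8 to 47.6), although it lies 7 nt from position 2901, the most frequent site of both libraries, whose ratio was 0.628. In 18S rRNA, position 199 had a ratio of 11.7 (10.5 to 13.2).

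Of the tests below, that of random placement was chosen before its result was seen and the others were chosen after. The positions beside 18S position 771 were also higher. End blur, in which reads of 1 cut are scattered over nearby positions, was set against the 5 most frequent mock sites of each rRNA in the poly I:C library. Position 770 held 40.6% as many reads as 771, while the larger neighbour at 1 nt held at most 14.3% of its peak at the 10 sites, which argues against a blur of the size seen at these sites as the source of the reads at 770. At 11 named sites at or over 10-fold that exceeded both neighbours, 771 among them, this share ran from 0.963% at 28S position 3065 to 90.6% at 28S position 4031, and it was 17.5% at 18S position 136, so a blur particular to some higher sites is not excluded. Positions 2 to 5 nt from 771 held 4.54% of its reads, and 4 of the 10 sites, all in 18S rRNA, held as much or more. The highest share, 73.0%, was at position 130, whose flank includes position 135, itself higher at a ratio of 12.4 (11.8 to 13.1). The next was 17.7% at position 1721. Blur 2 to 5 nt from 771 thus cannot be told apart from cuts there, since neighbours of the 10 sites can hold cuts of their own. Cuts at several neighbouring bonds after poly I:C, a blur set by the local sequence and a difference between single libraries also stay open.

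The 15 windows at least 2-fold higher held a median of 341 mock reads, against 26753 in the other 56, and mock density and ratio, computed from separate random parts of the mock reads, correlated across 71 windows with a Spearman's rho of -0.614. Both parts come from the same mock library, so the split removes shared counting error but not other deviations of that library. If a like number of added reads had fallen in every window, gains per 1000000 reads would be similar where mock reads are few. For the 10 windows with under 1000 mock reads that start inside the annotated rRNA, the largest gain was 714 times the smallest. Those 10 windows were chosen without regard to their ratio. The spread argues against equal gains only. A ratio divides by the mock reads, so unequal gains unrelated to mock density can also give a negative correlation, which was not tested. Counting noise of independent reads is also argued against, because the interval reached below 2 in only 2 of the 15 windows. These windows were picked by their ratio, and the interval does not cover duplicates from amplification, so noise of that kind was not tested. A candidate explanation is that poly I:C adds cuts in segments that are rarely cut without it. Large gains per 1000000 reads, however, lay in windows with few mock reads and in windows with many. 18S positions 701 to 800 gained 88320 on 4829 mock reads, and 28S positions 1001 to 1100 gained 22559 on 817. 18S positions 101 to 200 gained 42172 on 79550 mock reads, and 28S positions 4001 to 4100 gained 25395 on 242882. With 1 library per group, added cuts cannot be separated from a difference between libraries.

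From 28S position 3053 to 3067 the poly I:C library had 8 local maxima spaced 2 nt apart, with 30554 reads on them and 510 on the positions between. The mock library had 68 and 14 reads there. If reads of 1 cut had been placed at random among equivalent alignments of a repeat, the maxima would hold similar counts, but the highest held 18.4 times the lowest (counting interval 16.7 to 20.2). Runs of at least 4 such maxima with at least 100 reads each numbered 13 in the poly I:C library and 9 in the mock library, among them 7 maxima from 18S position 1374 to 1386 and 6 from 28S position 958 to 968 in both, and no chance value was computed. Cuts at a recurring bond of a dinucleotide repeat, and slippage in such a repeat during library preparation, may both give such a ladder, and neither was tested because no sequence was used.

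Whether the clusters of strongly higher sites lie near each other was tested at 1 distance. Of the 37 cluster peaks, 22 had another within 50 nt, and 2000 random placements among the compared positions gave a median of 18 and a central 95% range of 11 to 25, so no gathering beyond random placement was seen at this distance. Positions at most 10 nt apart had been merged first, so closer gathering was not tested.

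Positions beyond the annotated end were listed as well. In 18S rRNA 10 positions past 1869 held 49 mock reads and 163 poly I:C reads, and in 28S rRNA 3 positions past 5070 held 14 and 29.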
